A study of Drosophila melanogaster with 4 samples.

How the data were processed

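Open chromatin was profiled in single nuclei of fixed whole Drosophila melanogaster embryos by single-cell combinatorial indexing ATAC-seq, collected 2 to 4 h, 6 to 8 h and 10 to 12 h after egg laying. The labels put the 3 collection windows under 1 sample. Each file was given to the window in its name, which matched exactly 1 of the 3 stage labels of that sample. The 3 DNase-seq samples of the series, from whole-embryo, elav+ and Mef2+ nuclei at 6 to 8 h, were not analysed here.

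The deposited matrices held whole-number counts per region and cell, which the authors had not normalized as far as the values show. One matrix per window covered 53133 regions around accessibility summits, 151 to 1207 bp wide with a median of 176 bp. Another covered 83290 windows of 2 kb tiling the genome with gaps, and 136 summit regions had no window at their middle. Per the submitters' processing notes, coordinates are those of build dm3, and bcl2fastq 2.16, Trimmomatic 0.32, Bowtie2 2.2.3, SAMtools 1.1 and MACS2 2.1.1.20160309 were used for this sample. The roles of these tools, whether summits were called per window or on pooled reads, any duplicate removal and any shift of reads for the transposase cut are not given in the sources used here. In the summit matrices 36.9% to 38.5% of the deposited counts above 0 were even, and in the 2 kb matrices 81.7% to 82.8%, so counts were not read as independent fragments. A region was therefore taken as open in a cell when its count was at least 1, and this open call was the unit of all main results. Saturation at 1 call per region lowers ratios for regions open in most cells, and the size of that loss differs with depth.

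The series design states 23086 cells and the files held 23085, all of which were used. Every cell had at least 503 counts in the 2 kb matrix. Open calls per cell ranged from 57 to 17977. No cells were removed as doublets in the main results. The alternative left out cells above the 95th percentile of open calls of their window. No barcode was shared between windows. A deposited table of index tags, P1 to P4, divided the cells of each window into 4 technical parts of 1747 to 2012 cells, and these were used as a check within windows. They are parts of the same nuclei preparation as far as the labels say, and were not treated as replicates.

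For each pair of windows the level of a region was its number of open cells per 100000 open calls of the window. A region met the size rule when it was open in at least 5% of the cells of 1 of the 2 windows and its level differed at least 4-fold. The labels mark no replicate collections and do not say how libraries were divided. Each window was therefore treated as 1 library, and no test across cells was made. Ratios carry the exact 95% interval of 2 Poisson counts and shares carry the exact 95% Clopper-Pearson interval, and both cover counting error only. The regions named for each pair were the 10 with the largest ratio and the 10 with the smallest among those passing the 5% filter. Stretches were runs of at least 4 regions that met the rule in the same direction with gaps of at most 5000 bp. They were set against 1000 random draws of as many regions from those passing the filter. Positions are 1-based.

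Cells were clustered within each window from regions open in at least 1% of its cells. Calls were weighted by term frequency and inverse document frequency with a factor of 10000 and reduced by truncated singular value decomposition with 7 iterations, a setting that alters the clusters, to 30 components. This reduction is known as latent semantic indexing, LSI. The first component was left out because it followed depth, with a correlation across cells of 0.968 to 0.972 with log open calls. A graph of the 20 nearest cells was divided by the Leiden method at resolution 1, and clusters of at least 20 cells were counted. A region was specific to a cluster when its share of open calls was at least 4-fold that in the other cells of the window, with a pseudocount of 0.5, and it was open in at least 10% of the cluster's cells. Clusters were also made from autosomal regions alone. Cluster profiles of different windows were compared by Pearson correlation across regions, which are not independent replicates.

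The X share of a cell was its open calls on X as a percentage of those on X, 2L, 2R, 3L and 3R. The central minimum was read from a kernel density with a bandwidth of 0.5 points. The boundary of 16% between the 2 modes was set after the data had been seen. For values inside groups, cells of at least 1000 open calls lying more than 1 point below or above the minimum were called low-X and high-X cells. The late-pattern share of a cell was its open calls in autosomal regions at least 4-fold higher at 10 to 12 h than at 2 to 4 h, as a percentage of its calls in those and in the regions at least 4-fold lower. This score and its threshold of 50% were chosen after the data had been seen.

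The size rule was tested on simulated data for all 53133 regions with 200 altered regions per pair. It recovered 100% of regions raised 6-fold in all 3 pairs, and 100%, 100% and 98% of those lowered 6-fold for 6 to 8 h over 2 to 4 h, 10 to 12 h over 6 to 8 h and 10 to 12 h over 2 to 4 h. It called 0 regions altered 2-fold and 0 unaltered ones. The spread between replicate collections is not known from these data, so the simulation says nothing about calls that come from it. A first form of this simulation, which started from means that already differed between the windows, recovered fewer of the lowered regions and was replaced. Clustering was tested on simulated cells of 6 to 8 h depth over the 53133 regions, with 200 regions per group raised 8-fold. With 8 groups of 2400 cells in all and raised regions open in 2% to 10% of cells, 8 clusters were found, with an adjusted Rand index of 0.988, 99.9% of raised regions recovered and 0 others called. With 3 groups of 1500 cells in all, 3 clusters were found, with an index of 0.986 and 99.7% recovered. With 3 groups, 10 components and raised regions of any level from 3% of cells upwards, 6 clusters were found, the index was 0.667, 21.5% of raised regions were recovered and 3 others were called. The 8-group form was written after a poor result of this form. With 10 components alone, 5 clusters were found, with an index of 0.758 and 52.7% recovered, and with raised regions of any level alone, 3 clusters were found, with an index of 1 and 89.2% recovered. Clusters can thus be split further than the simulated groups when components are few, and some raised regions were missed when they were of any level. All simulated groups were of equal size with 200 raised regions each, and no simulation held a single group. The simulations therefore do not show how many clusters of the data divide like cells.

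Alternatives fixed before the data were examined were the unscaled share of cells, scaling by the median ratio, thinning to 1000 open calls per cell, leaving out the shallowest cells, filters of none or 10% of cells, a 2-fold rule, the 2 kb windows, Leiden resolutions of 0.5 and 2, 15 LSI components, keeping the first component, the 20000 most often open regions, leaving out the deepest cells, and X shares in 2 kb windows or in cells above the median depth. Alternatives added later were counts in place of open calls, each index tag alone, the late-pattern cells left out, clusters from autosomes alone, from thinned cells, from the same cells without thinning or with 5 or 10 iterations of the decomposition, cluster-specific regions at resolution 2, and X shares in cells of at least 1000 calls. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The only gene table used here is of another genome release than dm3, so regions are given by coordinates without gene names, clusters stay numbered, and the planned lists of marker genes were not analysed here. Whether a region lies in an exon, an intron or a promoter was not analysed here for the same reason. In the 2 kb matrices, 19302 windows on unplaced sequence held 0 open calls.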

Results

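The regulatory DNA of developing Drosophila melanogaster embryos was surveyed one nucleus at a time. In single-cell combinatorial indexing ATAC-seq, a transposase inserts into accessible DNA and combinations of barcodes mark the fragments of each nucleus. Whole embryos were collected 2 to 4 h, 6 to 8 h and 10 to 12 h after egg laying, intervals that run from the blastoderm and gastrulation to the differentiation of tissues. The files held 8024, 7880 and 7181 cells for the 3 windows. Median open calls per cell, the number of summit regions with a count, were 2607, 3255 and 2533, and the windows held 25063554, 29235084 and 20184304 open calls in all. The labels mark no replicate collections, so each window was treated as 1 library and values carry intervals for counting error only. Within a window, the 4 index tags gave region levels that correlated across regions with r from 0.968 to 0.983. Positions are in build dm3, and the genes at these positions were not analysed here.

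The first question was which regions were more or less accessible as development proceeded. Between the earliest and the latest window, 2271 of 25586 regions were at least 4-fold lower at 10 to 12 h and 1127 were at least 4-fold higher. The largest losses were regions open in a sizeable share of early nuclei and in almost none later. The region at 2R 15549073-15549444 was open in 27.8% of cells at 2 to 4 h, 1.62% at 6 to 8 h and 0.487% at 10 to 12 h, a 51.4-fold lower level (95% interval 36.8 to 74.0). The region at 3L 13371401-13371783 went from 26.8% through 1.22% to 0.529% of cells and was 45.6-fold lower. On X, 15540870-15541124 was open in 15.1%, 1.02% and 0.265% of cells and was 51.5-fold lower (32.8 to 85.8), and its neighbour at 15541136-15541286 was 50.1-fold lower. Also on X, 18197650-18197824, was 47.4-fold lower, and 3R 15164763-15164963 was 42.6-fold lower. Of the 10 named regions with the largest losses, 4 lay within one stretch of 2L, between 6373217 and 6374694, with levels 40.6-fold to 44.7-fold lower.

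The regions with the largest gains started from about 1% of cells. The region at 3R 22087126-22087402 was open in 1.02%, 4.10% and 15.5% of cells in the 3 windows, a 16.8-fold higher level at 10 to 12 h (13.4 to 21.3). The region at 3L 10733218-10733508 had 1.32%, 4.14% and 19.9% of cells and was 16.7-fold higher (13.7 to 20.5). On 2R, 6107663-6107873 was 16.7-fold higher and 6047296-6047717 was 15.1-fold higher, the latter open in 21.5% of cells at 10 to 12 h. A pair of regions on 3R, 22287165-22287369 and 22288176-22288349, were 15.5-fold and 15.4-fold higher. The X regions 15192653-15192885 and 1864611-1864899 were 15.1-fold and 14.9-fold higher, 3L 22828527-22828799 was 14.8-fold higher and 3R 7022688-7022856 was 14.5-fold higher. With the unscaled share of cells in place of the share of open calls, 894 regions were higher and 2584 lower. In 2 kb windows 240 were higher and 576 lower.

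**Figure D1:**
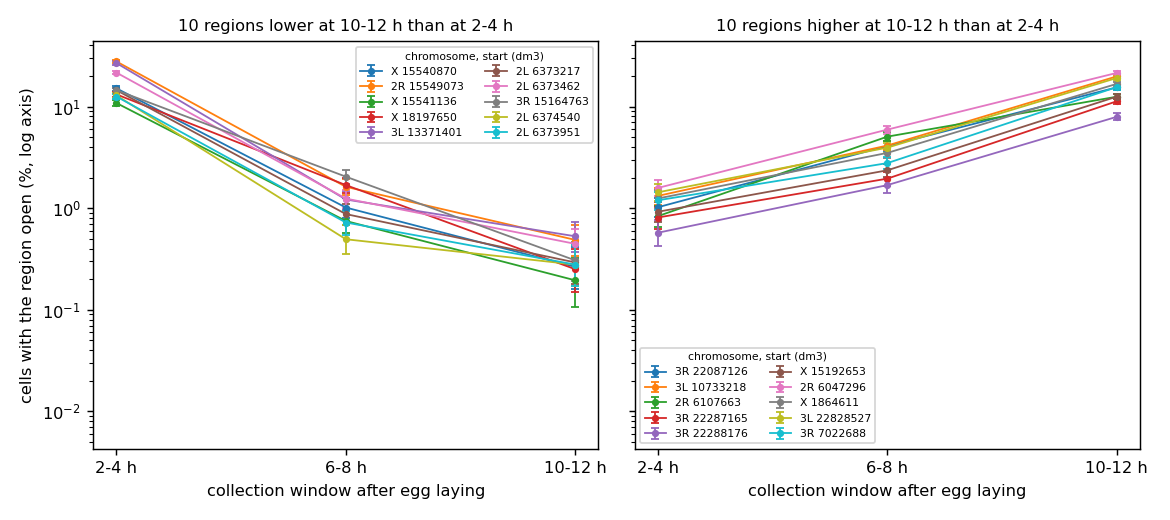
Percentage of cells with a region open (log axis) in each collection window, for the 10 named regions lower (left) and the 10 higher (right) at 10 to 12 h than at 2 to 4 h. Points are shares of all cells of the window and bars are exact 95% binomial intervals for counting error. The lower set lies below 1% of cells at 10 to 12 h, and the higher set starts below 2% at 2 to 4 h.

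The order of losses and gains depended on the scaling. With levels scaled to open calls, 1362 of the 2271 lower regions (60.0%) had passed the midpoint of their log2 difference by 6 to 8 h, and 680 were already 4-fold lower then. Their median share of open cells was 9.87%, 3.74% and 1.2% in the 3 windows. Of the 1127 higher regions, 337 (29.9%) had passed the midpoint by 6 to 8 h and 46 were already 4-fold higher. Their median shares were 1.72%, 3.91% and 8.76%. Scaling by the median ratio put 65.8% of the lower and 24.8% of the higher regions past the midpoint. In unscaled shares of cells the order was turned, with 947 lower regions (41.7%) and 563 higher regions (49.96%) past it, although 480 lower and 95 higher regions were already 4-fold apart. These sets were picked on the outer windows, so the position of the middle window was free to fall on either side.

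A part of the regions that met the size rule lay in runs along the chromosomes, and most did not. Lower regions formed 140 stretches of at least 4 regions, holding 908 of the 2271, and higher regions formed 51 stretches holding 270 of the 1127. When as many of the tested regions were drawn at random 1000 times, with their positions kept, such stretches held at most 125 and 24 regions. The draws took each region as independent of its neighbours. They therefore cannot tell a change over a domain from several regions within a single open element. All 11 regions tested between 6373217 and 6377502 on 2L were lower at 10 to 12 h, and their mean share of open cells was 15.7%, 0.874% and 0.422%. The longest lower stretch, 31.1 kb at 3R 15155683-15186797, held 19 lower regions among 21 tested, with a median 19.6-fold difference. At 3L 14936555-14966623, 25 of 30 regions were lower, but their mean share was 17.4% at 2 to 4 h, 13.8% at 6 to 8 h and 2.30% at 10 to 12 h, so most of the difference fell after 6 to 8 h. At 2L 15728112-15744075 all 19 regions tested were lower, with a median of 11-fold. Among higher stretches, 3L 17954797-17966360 held 16 of 17 regions with a median of 6.99-fold, X 1857520-1870364 held 11 of 11 with 7.97-fold, and 3L 9685770-9690164 held 7 of 7 with 10.4-fold. The longest, 17.3 kb at 2R 6098463-6115757, held 12 of 13 with a median of 8.00-fold. These stretches were chosen after their values had been seen.

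**Figure D2:**
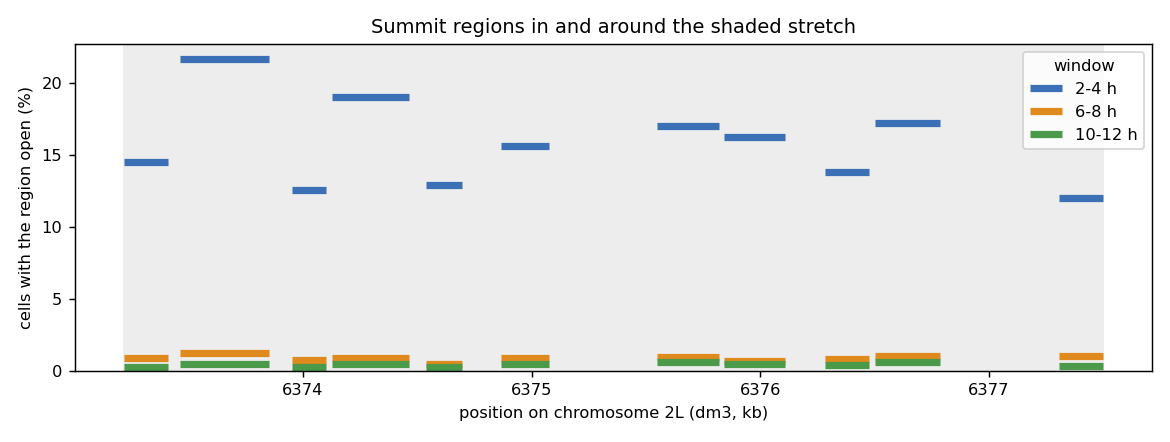
Percentage of cells with each summit region open (vertical axis) along chromosome 2L (horizontal axis, dm3, kb), one bar per region drawn over its own width and coloured by collection window. The shaded stretch runs from 6373217 to 6377502, and all 11 regions in it are lower at 6 to 8 h and at 10 to 12 h than at 2 to 4 h.

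From 2 to 4 h to 6 to 8 h the differences were mostly losses. Of 26731 regions tested, 701 were at least 4-fold lower at 6 to 8 h and 63 at least 4-fold higher. The largest loss was at 2L 6374540-6374694, open in 12.9% of cells at 2 to 4 h and 0.495% at 6 to 8 h, a 31.0-fold lower level (22.5 to 43.8). Of the 10 named losses, 6 lay in the same 2L stretch. The others included 3L 18586778-18586950, which was 23-fold lower, and 2R 15549545-15549695, which was 20.7-fold lower. Gains were smaller, led by 3R 12034082-12034232, open in 0.823% and 6.43% of cells and 6.59-fold higher (5.09 to 8.65). The region at 3L 725420-725622 had 2.18% and 15.6% of cells and was 6.03-fold higher, 3R 15715747-15715923 was 5.86-fold higher, and 2L 3888322-3888504 was 6.23-fold higher. Lower regions formed 34 stretches holding 198 regions, and higher regions formed none.

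The excess of losses between these windows was smaller without scaling to open calls. Then 165 regions were higher and 484 lower, so that 25.4% of the regions meeting the rule were higher, against 8.25% in the main count. Scaling by the median ratio gave 31 higher and 822 lower, or 3.63% higher. In 2 kb windows 0 were higher and 102 lower, and all 10 named gains were under 4-fold there. The median region differed by 0.11 (log2) under scaling to open calls and by 0.36 without it.

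From 6 to 8 h to 10 to 12 h, gains and losses were closer in number. Of 25625 regions tested, 294 were at least 4-fold higher at 10 to 12 h and 350 at least 4-fold lower. The largest gain was at 3R 6210302-6210602, open in 0.812% of cells at 6 to 8 h and 5.68% at 10 to 12 h, a 9.23-fold higher level (7.08 to 12). On the same arm, 21943276-21943454 was 8.26-fold higher and 22287165-22287369, with 1.95% and 11.3% of cells, was 7.63-fold higher. The largest losses were at 3R 15169665-15169896, with 6.90% and 0.376% of cells and a 13.9-fold lower level (9.45 to 21.3), and at 3L 1431491-1431694, which was 12.6-fold lower. The region at 2R 9456033-9456183 went the furthest in share of cells among the 4 largest losses, from 17.3% to 1.39%, and was 9.41-fold lower. An 8-region stretch at 3R 27527695-27530938 had mean shares of 5.65%, 14.9% and 1.95% in the 3 windows. Stretches held 31 of the 294 higher and 74 of the 350 lower regions.

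Here the split turned further with the scaling. Without scaling to open calls, 89 regions were higher and 748 lower, so that 10.6% of the regions meeting the rule were higher, against 45.7% in the main count. Scaling by the median ratio turned it the other way, to 336 higher and 293 lower, or 53.4% higher. Gains also outnumbered losses in 2 kb windows, with 28 higher and 8 lower, and without the filter, with 763 higher and 544 lower. The median region differed by -0.06 (log2) with the scaling and by -0.46 without it.

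Some regions were most open in the middle window. By a rule set after the data were seen, 169 regions had at least a 2-fold higher level at 6 to 8 h than in either other window, and 30 had at least a 2-fold lower one. The former had to be open in at least 5% of cells at 6 to 8 h, the latter in at least 5% in an outer window. These numbers hold for levels scaled to open calls and were not counted with other scalings. Unscaled shares shift levels at 6 to 8 h upwards against both other windows, and the median ratio shifts them downwards. The top region, 3R 27528674-27528842, was open in 3.07%, 15.2% and 1.99% of cells. The region at 2R 5596226-5596376 was open in 2.73%, 14.6% and 3.19%, and X 5916826-5916976 in 1.3%, 5.36% and 0.975%.

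Chromosomes differed in how they took part. The heterochromatic arms of the assembly took 1.14%, 0.721% and 0.709% of open calls in the 3 windows. Of their 254 regions tested between 2 to 4 h and 10 to 12 h, 52 (20.5%) were lower and 0 higher, beside 9.32% lower and 4.54% higher on 2L, 2R, 3L and 3R. On chromosome 4, which is largely heterochromatic, 13 of 459 regions were lower and 2 higher. X regions took 14.7% of open calls at 2 to 4 h, 15.9% at 6 to 8 h and 16% at 10 to 12 h.

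Single cells were placed on the same axis of early and late regions. The late-pattern share used 952 autosomal regions of the higher set and 1962 of the lower set, in cells of at least 1000 open calls. Its median was 5.54% at 2 to 4 h, 27.8% at 6 to 8 h and 78.7% at 10 to 12 h, with quartiles of 3.73% and 8.18%, 17.0% and 46.9%, and 70.2% and 85.1%. The order of the outer medians follows from how the regions were picked. Among 2 to 4 h cells, 213 of 6677 cells (3.19%, 2.78 to 3.64) had a share of at least 50%, and 99 of them at least 75%, while 6230 cells (93.3%) were under 20%. The 213 cells are a range of this score and not a type, and 92 further cells lay between 30% and 50%. With these 213 cells left out, the regions at least 4-fold higher at 6 to 8 h than at 2 to 4 h numbered 107 in place of 63. The cells were picked for calls in regions that are higher later, so a larger count was favoured by the choice.

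**Figure D3:**
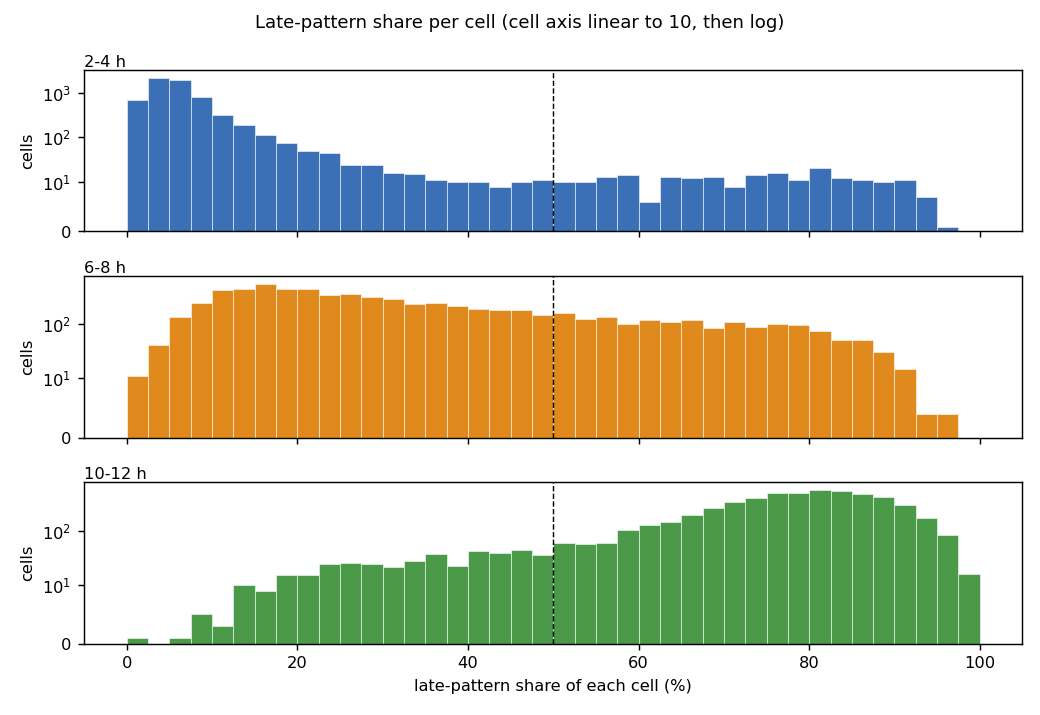
Number of cells (vertical axis, linear up to 10 and logarithmic above) by late-pattern share in percent (horizontal axis), in bins of 2.5 points, for cells of at least 1000 open calls in each collection window. The dashed line marks 50%. At 2 to 4 h most cells lie below 20%, and 213 cells lie at or above the line.

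The second question was what groups of cells each window held. Clustering within windows gave 20 clusters at 2 to 4 h, 24 at 6 to 8 h and 22 at 10 to 12 h, and no cluster held most of a window. With 5 iterations of the decomposition in place of 7 they numbered 19, 21 and 22, and with 10 iterations 19, 24 and 22. The largest held 11.2% of cells (10.5 to 11.9), 8.92% (8.30 to 9.57) and 9.97% (9.29 to 10.7). Median open calls in these largest clusters were 1524, 2472 and 2863.5, beside 2607, 3255 and 2533 over all cells. Cluster medians ran from 1460 to 3993 at 2 to 4 h, 1499 to 5122.5 at 6 to 8 h and 1183 to 6475 at 10 to 12 h. Clusters thus differed in depth, and how far depth divided them was not tested. Regions specific to at least 1 cluster numbered 2313, 7297 and 9834. At 2 to 4 h, 4 of the 20 clusters had no specific region and the median cluster had 47.5, while the medians were 273 at 6 to 8 h and 504.5 at 10 to 12 h. These are descriptions within each window, since the regions that define clusters also differ between windows.

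Single regions had a much higher level in some clusters than in other cells, though those named here were open in a minority of the cluster's cells. At 10 to 12 h, X 18080030-18080180 was open in 12.5% of the 281 cells of cluster 13 and 0.130% of other cells, an 82.5-fold level. In the 133 cells of cluster 20 of that window, X 7160277-7160434 was open in 17.3% against 0.369%, a 68.9-fold level. At 6 to 8 h, 2L 14133272-14133422 was open in 13.8% of the 123 cells of cluster 21 and 0.232% of others, a 64.7-fold level, and cluster 21 had the most specific regions of its window, 1897. The same X 7160277-7160434 led cluster 9 of 6 to 8 h, open in 14.1% of its 384 cells and 0.774% of others. In the earliest window, the 92 cells of cluster 20 had 824 specific regions, led by X 1276873-1277023 with 15.2% against 0.605%. The 898 cells of the largest 2 to 4 h cluster were led by 3 regions on 2L between 4683307 and 4687843, each open in 12.8% to 16% of its cells. These regions were chosen after their values had been seen, and they define the clusters, so they are not evidence for them.

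Part of the division followed the X chromosome. Clusters in which over 80% or under 20% of the cells with at least 1000 calls lay below an X share of 16% numbered 7, 5 and 6 and held 39.6%, 26.1% and 33.6% of all cells. When only autosomal regions were clustered, such clusters numbered 1, 0 and 0, among 16, 22 and 19 clusters. After thinning to 1000 open calls per cell, 10, 7 and 8 clusters were found with 185, 137 and 411 specific regions. The same cells without thinning gave 17, 24 and 22 clusters with 2045, 8318 and 10517 specific regions, so both numbers depend on depth. With the main clusters kept for these cells, specific regions numbered 2880, 7907 and 10913 without thinning and 450, 805 and 1707 with it.

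Whole embryos mix males with 1 X chromosome and females with 2, and the X share of open calls per cell fell into 2 groups in every window. In the earliest window 54.0% of cells (52.9 to 55.1) lay below the central minimum, at 6 to 8 h 47.6% (46.5 to 48.7) and at 10 to 12 h 49.2% (48.0 to 50.4). The lower mode was at 11.5%, 12.9% and 13.0% of open calls, and the upper mode at 18.45%, 19% and 19.2%. The minimum held 31.9%, 26% and 28.2% of the density at the lower of the 2 modes. Single index tags at 2 to 4 h placed 49.95% to 56.9% of cells below their minimum, and cells above the median depth placed 47.4%, so the share at that window moved by more than counting error. The minimum was found anew each time. It lay at 15.65% in all cells, at 14.65% to 16.1% in single tags and at 14.75% in the deeper cells. The interval of the share does not cover the position of the minimum.

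Low-X and high-X cells were divided by their X share, so a lower level on X in low-X cells follows from the division, and the values below describe its size and its evenness over X regions. The median X region of 2 to 4 h low-X cells had 0.561 of its level in high-X cells, with quartiles of 0.527 and 0.601, and 99.7% of 3300 X regions were lower in low-X cells. The medians were 0.601 over 3905 X regions at 6 to 8 h and 0.581 over 3146 at 10 to 12 h, while autosomal regions had medians of 1.00, 0.998 and 0.996. Pooled over regions, the X-to-autosome ratio of low-X cells was 0.566 of that of high-X cells at 2 to 4 h (0.561 to 0.570 over the 4 index tags), 0.623 at 6 to 8 h (0.619 to 0.625) and 0.607 at 10 to 12 h (0.600 to 0.613). In 2 kb windows it was 0.596, 0.706 and 0.692. The numbers of cells within 1 point of the minimum were 510, 538 and 403, and their median open calls were 1.05, 0.977 and 1.13 times those of the other cells.

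**Figure D4:**
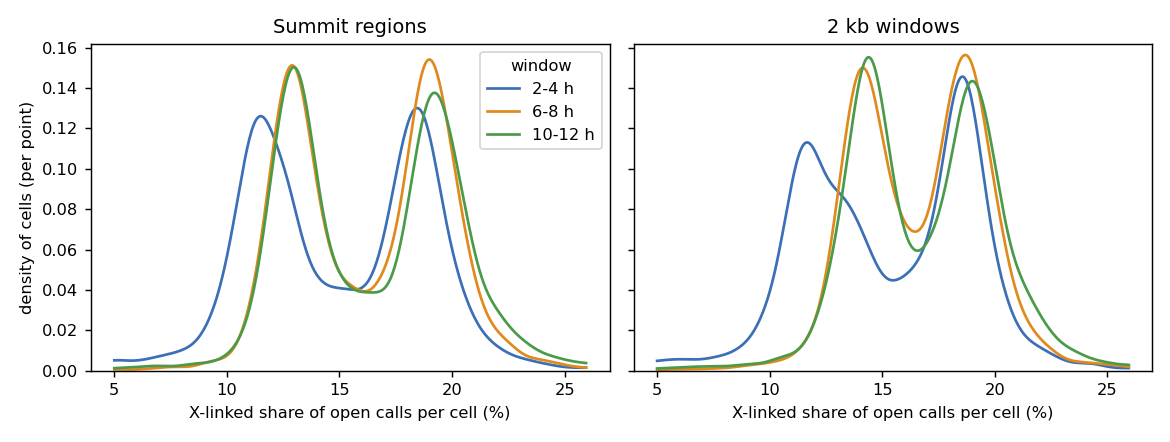
Density of cells (vertical axis, per percentage point) by the X-linked share of their open calls in percent (horizontal axis), from summit regions (left) and 2 kb windows (right), with 1 line per collection window. Each window has a lower and an upper mode, and the lower mode at 2 to 4 h lies to the left of the other windows.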

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

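All tests in this part were chosen after the Y-linked values had been seen. The 166 Y-linked windows of 2 kb entered no comparison of the report, and they held open calls in every collection window. Over all cells they took 21.5 of 100000 open calls at 2 to 4 h (95% interval 21.1 to 21.9, counting error only), 7.42 at 6 to 8 h (7.18 to 7.67) and 4.33 at 10 to 12 h (4.10 to 4.56).

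The lower Y level after 2 to 4 h was set against 3 explanations. A smaller share of low-X cells later was argued against, since within low-X cells alone the level was 41.1, 14.5 and 7.74 per 100000 in the 3 windows, a ratio of 0.188 between the last and the first. Repeats of other chromosomes placed on Y were argued against by high-X cells, whose level at 2 to 4 h was 1.85 per 100000, or 0.0450 of that of low-X cells. A lower level of heterochromatin at large stays open for part of the pattern, because the other heterochromatic arms of high-X cells at 10 to 12 h had 0.533 of their level at 2 to 4 h, while those of low-X cells had 2768 and 1367 per 100000 at 2 to 4 h and 10 to 12 h, a smaller difference than on Y. Age of the embryos stays open as untested. It cannot be told apart from the collection, because the labels mark no replicate collections within a window.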

How the results depend on the processing

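The settings of index tags, counts, left-out late-pattern cells, autosomes, thinned clusters, cells of at least 1000 calls, iterations of the decomposition and resolution 2 for specific regions were chosen after the results had been seen. Of 82 alternative counts of regions between windows, 44 stayed within 1.5 times the main count and 38 did not. Counts were taken as kept within 1.5 times the main count, and shares of cells as kept inside the 95% interval of the main share. The named results were 60, on 54 distinct regions, since 6 regions were named in 2 pairs. Of the 60, 0 changed sign and 0 came under 4-fold with unscaled shares, thinning, the median ratio, counts, the shallowest cells left out or any single index tag, the lowest being 4.13-fold. Unscaled shares and the median ratio shift every log2 ratio of a pair by the same amount. For regions picked as the most extreme they are therefore no separate check. Thinning, counts, left-out cells, index tags and the 2 kb windows reuse the cells on which the regions were picked. They are therefore no independent support either. Of the 58, on 52 distinct regions, with a 2 kb window at the middle, 0 changed sign there and 19 came under 4-fold, down to 2.27-fold. These 19 were all 10 gains from 2 to 4 h to 6 to 8 h, and 2 gains and 7 losses from 6 to 8 h to 10 to 12 h. Most alternatives with other counts test other regions, use another size rule or shift all ratios of a pair by construction. For the rest the cause was not tested, save that the choice of late-pattern cells favours gains without them. No paired analysis was possible because the labels mark no replicate collections within a window. The 3 alternatives for marker gene loci were not run, since gene positions in dm3 were not used here. Depth limits what regions open in few cells can show, and the number of clusters with it, which was 17, 24 and 22 in the cells used for thinning before their calls were thinned.

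Counts are given as higher and lower, for 6 to 8 h over 2 to 4 h, 10 to 12 h over 6 to 8 h and 10 to 12 h over 2 to 4 h in turn, against 63 and 701, 294 and 350, and 1127 and 2271 in the main results. Thinning to 1000 open calls, which leaves fewer regions past the 5% filter, gave 15 and 203, 27 and 40, and 205 and 558. A filter of 10% of cells gave 39 and 378, 98 and 134, and 444 and 1120. A 2-fold rule gave 1600 and 2558, 1685 and 1982, and 3490 and 4774. The 2 kb windows, which average over closed DNA, gave 0 and 102, 28 and 8, and 240 and 576, so that the second pair had more gains than losses. It also had more gains with the median ratio, 336 and 293, and with no filter. No filter gave 1136 lower in the first pair, 763 and 544 in the second and 1938 and 3472 in the third. The unscaled share of cells gave 165 higher in the first pair and 89 higher and 748 lower in the second. Leaving out the scaling shifts every log2 ratio of a pair by the same amount. The median region moved from 0.11 to 0.36 in the first pair and from -0.06 to -0.46 in the second. Higher regions in the first pair numbered 31 with scaling by the median ratio, 143 with counts in place of open calls and 107 without late-pattern cells. They numbered 108 in index tag P1 and 102 in tag P4, and those in the second pair numbered 446 with counts. The median ratio also shifts every log2 ratio of a pair by the same amount, and the choice of the late-pattern cells favours more gains once they are left out. For counts and index tags the cause was not tested.

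The largest cluster moved in 25 of 33 alternatives, and the cause was not tested. At 2 to 4 h, 6 to 8 h and 10 to 12 h in turn it held 20.0%, 13.8% and 14.3% of cells at resolution 0.5, 8.67%, 6.18% and 7.59% at resolution 2, 9.05%, 11.3% and 7.92% with 15 components, 13.9%, 13.2% and 9.08% with the 20000 most often open regions, 12.8%, 12.9% and 15% from autosomes, 19.0%, 24.3% and 21.5% after thinning, and 13.8%, 10.9% and 14.1% in the same cells without thinning. It held 12.4% at 2 to 4 h without the deepest cells and 11.2% at 10 to 12 h with the first component kept. With 5 iterations it held 11.1% at 6 to 8 h and 8.84% at 10 to 12 h. The number of clusters moved past 1.5 times only after thinning, to 10, 7 and 8, and ranged from 7 to 34 over all alternatives, with 29, 34 and 31 at resolution 2 and 30 at 10 to 12 h with 15 components. Specific regions numbered 9224, 17806 and 19872 under a 2-fold rule and 185, 137 and 411 after thinning, and at 2 to 4 h 1502 at resolution 0.5 and 4014 at resolution 2.

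The share of cells below the minimum of X share moved in 12 of 21 alternatives, between 45.1% and 56.9%. The minimum was found anew in each alternative, so the dividing point moved too. At 2 to 4 h it lay at 14.65% in tag P2, 15.05% in P1, 15.3% in P4 and 16.1% in P3, beside 15.65% in all cells. The shares of these tags rose in the same order. How much of the shift came from the dividing point was not tested. In the 2 kb windows the share of cells was 51.2% at 2 to 4 h and 47.4% at 10 to 12 h. In cells above the median depth it was 47.4%, 45.6% and 45.1% in the 3 windows. In tag P1 it was 50.4%, 45.3% and 50.9%. At 2 to 4 h it was 49.95% in tag P2, 56.9% in P3 and 52.3% in P4, and at 10 to 12 h it was 46.8% in P3.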

Other observations

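The tests chosen only after the results had been seen were those on cluster matches of late-pattern cells, the bands of depth, the 2 kb windows, the high-X cells and the ratio of low-X to high-X cells. The overlaps and cluster correlations of the first paragraphs are descriptions that were also added after the data had been seen. The planned test of saturation by thinning, at 1.33 points, was replaced because random thinning keeps the expected X share.

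Regions that were more open in a later window were compared with tested regions of like level for cluster specificity in the earlier window. Of the 294 regions at least 4-fold higher at 10 to 12 h than at 6 to 8 h, 259 (88.1%) were specific to at least 1 cluster at 6 to 8 h, beside 73.1% for tested regions of like level. At 10 to 12 h itself, 12.6% of them were specific to a cluster, beside 8.22%. Of the 63 regions higher at 6 to 8 h than at 2 to 4 h, 42 (66.7%) were cluster-specific at 2 to 4 h, beside 22.5%, and of the 1127 higher at 10 to 12 h than at 2 to 4 h, 26.4% were, beside 17.9%. With clusters made from autosomes these shares at the earlier window were 82.0%, 42.9% and 13.1%, beside 67.5%, 14.1% and 9.10%. In the same order, 12.3% of 350, 5.56% of 701 and 2.77% of 2271 lower regions were cluster-specific at the earlier window, beside 6.86%, 1.52% and 1.67%. None of these differences was tested. Regions under 5% of cells in the earlier window count as tested only when they pass the filter in the later one, so the reference was limited to tested regions. The reference includes the compared regions themselves, and at low levels it can consist largely of them. It is therefore not an independent comparison. Whether late-pattern cells carried these regions was not tested.

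Cluster profiles matched better between the later windows than between the earlier ones. Among 19 autosomal clusters of 10 to 12 h, the median correlation across regions with the closest cluster of 6 to 8 h was 0.646 (0.189 to 0.834), 14 reached 0.5 and 9 were closest in both directions. Among 22 autosomal clusters of 6 to 8 h, the median with the closest 2 to 4 h cluster was 0.460 (0.198 to 0.708), 10 reached 0.5 and 7 were closest in both directions. The closest match was between cluster 2 of 10 to 12 h, with 684 cells, and cluster 4 of 6 to 8 h, with 733 cells. Their median open calls were 1247.5 and 2472, beside 2533 and 3255 in their windows. The number of clusters differs between windows, and the difference between the medians was not tested.

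The 213 cells of 2 to 4 h with a late pattern were set against several explanations. A pair of nuclei of different age under 1 barcode was argued against for the set as a whole, since these cells had 0.722 of the median open calls of the others. This median cannot exclude pairs in which the early nucleus was shallow, because it would add few calls. The 92 cells of 2 to 4 h between 30% and 50%, where more even pairs could lie, were not tested. Nuclei drawn at random from the 10 to 12 h window were argued against by the clusters of that window to which the cells came nearest, whose distribution lay 29.3% from that of late-pattern 10 to 12 h cells, beyond the highest of 1000 random draws at 17.1%, and 26.3% beside 19.5% for 10 to 12 h cells of index tags left out of the cluster profiles, with 186 late-pattern cells and all cells thinned to 1000 calls. The share of the cells with a barcode of a later window, 0%, decided nothing, because no barcode was shared between windows, and neither did the 3.19% of cells left when regions were chosen on other index tags, because choosing regions on the scored cells works against a late pattern in them. Embryos older than their window may have been in the collection, as a hypothesis that the spread of the cells over clusters leaves open. The cells came nearest to 16 clusters, of which 8 had at least 5 of them, with at most 28.6% nearest to any cluster. Nuclei from the 6 to 8 h window were not tested.

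In low-X cells the median X share was 1.34 points lower at 2 to 4 h than at 10 to 12 h, with values of 11.6% and 13.0%. Saturation at different depth and the choice of summit regions were argued against, since the difference was 1.12 to 1.76 points in 4 bands of cells of like depth and 2.25 points in 2 kb windows. A shift of X-linked regions in every cell stays open for part of it. In summit regions high-X cells differed by 0.828 points in the same direction. In 2 kb windows their medians were 18.7% at 2 to 4 h and 19.2% at 10 to 12 h, beside 12.1% and 14.3% in low-X cells. There the shift in high-X cells was a smaller part of that in low-X cells than in summit regions. The ratio of low-X to high-X cells decided nothing about 1 common factor. Its gap of 0.0299 between the index tags of the 2 windows sets windows without marked replicates against technical parts. Within 2 to 4 h, X share was 11.3% in the low-X cells up to the 25th percentile of late-pattern share and 12.1% in those from the 75th, beside 18.5% and 18.9% in high-X cells, a contrast of 0.479 points. A hypothesis was found and tested on the same data. X-linked regions of cells with 1 X chromosome may become relatively more open after 2 to 4 h, as dosage compensation in males would do. But the ratio of low-X to high-X cells was 0.566, 0.623 and 0.607 in the 3 windows. It was thus not higher at 10 to 12 h than at 6 to 8 h. Age also cannot be told apart from the collection, because the labels mark no replicate collections within a window.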
